A study of Mus musculus with 12 samples.

How the data were processed

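Whole lungs of melanoma-bearing C57BL/6J mice were profiled by RNA sequencing in 12 libraries, 3 in each of 4 groups: young mice given anti-PD-1, aged mice given a control antibody, aged mice given anti-PD-1, and aged mice given anti-PD-1 with anti-IL-21R (the combination group). RNA was extracted with Trizol and RNeasy columns and made into directional poly(A) libraries with the NEBNext Ultra II kit, per the labels' protocols. The values used are raw read counts per gene as deposited, 1 column per library, with no normalization applied by the authors according to the file header. Reads were processed with bcl2fastq 1.8.4, Trimmomatic, HISAT2 and featureCounts 1.6.3 against mm10, per the submitters' processing notes, which as used here give neither the options nor the annotation release nor the strand setting. Gene symbols, coordinates and gene ontology terms were taken from the annotation columns deposited with the counts.

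Counts summed to between 16021877 and 22058620 per library. Genes were kept by the edgeR function filterByExpr by group (minimum count 10, minimum total count 15), which left 18556 of 49585. Libraries were scaled by TMM, and CPM values are TMM scaled. A single edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion and 4 group means was fitted to the 12 libraries, with 8 residual degrees of freedom, a common biological coefficient of variation of 0.156 and a median prior of 6.11 degrees of freedom. Each comparison was a two-sided F test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were aged against young anti-PD-1, aged anti-PD-1 against aged control, combination against aged anti-PD-1, and combination against aged control. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so single values were compared through the fitted model only. Replicate numbers were not used as pairs: residuals of libraries with the same number had a median correlation of -0.0120 across genes over 18 pairs.

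The groups, comparisons, tests, 50 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover immune and structural cell types, signalling responses and technical classes, and they were drawn up with knowledge of the subject of the study. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. The naming rule took 6 genes in every comparison (Pdcd1, Cd274, Il21, Il21r, Cxcl13 and Cxcr5), the 10 higher and 10 lower called genes with the largest fold change among those with an average log2 CPM of at least 0 and no overlap between groups, and up to 4 called or 2 uncalled members per list; predicted genes and receptor segments were left out of the second part. From these, a selection is printed, and 1 gene that the rule names is not reported here. Terms for biological processes were tested in the same way with camera and were chosen for print after their values were seen.

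The test was tried on simulated counts with 200 genes changed. It called 112, 141, 135 and 130 genes there in the order of the comparisons. The p that passes the adjustment depends on how many genes change, so the rates below do not measure recovery in the real comparisons. Changes of 2-fold were recovered in 50.7% of cases for aged against young anti-PD-1 (18337 genes), 71.6% for anti-PD-1 against control (18333 genes), 67.2% for combination against anti-PD-1 (18363 genes) and 61.2% for combination against control (18346 genes). Changes of 1.5-fold were recovered in 17.9%, 23.9%, 26.9% and 29.9% in the same order, and false calls made up 5.36%, 8.51%, 7.41% and 7.69% of the calls.

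Alternatives tried were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, scaling without immunoglobulin, haemoglobin and mitochondrial genes, no filter, a filter at a mean CPM of at least 1, replicate number as a block, fits of only the 2 groups compared, and leaving out each library in turn. Removal of a trend on exon length and GC content (GENCODE M21, known for 99.8% of genes tested) and a clock gene score as a covariate were added after the data were seen. Overlaps between comparisons that share libraries were set beside 100 simulations without any effect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.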

Results

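RNA from the whole lung of C57BL/6J mice with an MO4 melanoma under the skin was sequenced after poly(A) selection. The 12 libraries formed 4 groups of 3. Mice of 2 months received an antibody against the checkpoint receptor PD-1 (young anti-PD-1 group). Mice of 22 months received an isotype-matched rat antibody (aged control group), anti-PD-1 (aged anti-PD-1 group), or anti-PD-1 together with an antibody against the IL-21 receptor (combination group). PD-1 restrains activated T cells, and IL-21 is a cytokine made chiefly by CD4 T cells that acts on B and T cells. Days 3, 7 and 11 after tumour inoculation are the injection days that the labels give for anti-PD-1 and control antibody. Counted reads per library ran from 16021877 to 22058620 over the 12 libraries. Of 49585 genes, 18556 had enough counts to be tested. A gene is called below where its adjusted p (edgeR quasi-likelihood test, Benjamini-Hochberg over all genes tested) was under 0.05. Fold changes are log2 values ± SE from that fit with 3 libraries a group. The SE was derived as the absolute log2 fold change divided by the square root of its F statistic. Nothing in the labels states that each library came from its own mouse, so the p-values measure only the spread between these samples. That spread went beyond counting noise: the chi-square per degree of freedom between libraries of a group ran from 9.39 to 46.9. How much of it is technical is not known.

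The make-up of the libraries differed between groups. Mitochondrially encoded transcripts took 6.76 ± 0.628% of the counts in the young anti-PD-1 group, 8.56 ± 1.62% in the aged control group, 9.35 ± 2.18% in the aged anti-PD-1 group and 13.4 ± 1.72% in the combination group (SD, n = 3 each). Haemoglobin transcripts took 1.40 ± 0.125%, 1.65 ± 0.364%, 1.16 ± 0.131% and 2.79 ± 1.12% in the same order. Immunoglobulin transcripts took 0.0462 ± 0.00103%, 0.232 ± 0.139%, 0.391 ± 0.0970% and 0.441 ± 0.187%. The first principal component of log CPM held 27.4% of the variance and set the 3 young libraries (46.3 to 48.2) apart from the 9 aged ones (-34.5 to -4.12). The second held 19.6% and set the 3 aged anti-PD-1 libraries (33.5 to 43.8) apart from the 9 others (-29.2 to 5.85). The clock gene Per3 stood at 34.1 ± 18.4 CPM in the aged anti-PD-1 group, against 12.3 ± 2.14 in the young, 10.4 ± 2.66 in the aged control and 9.38 ± 1.63 in the combination group. A score from 11 clock genes (activators less repressors and output genes, in log2 CPM) did not set all 3 libraries of that group apart: it was -0.823, -3.00 and -2.07 in its libraries, and -0.925 in the third combination library. The labels give no hour of collection and no batch.

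The first comparison asked how the lungs of aged and young mice differed under the same anti-PD-1 treatment. Most genes of the antibody, B cell, follicular helper and platelet lists rose with age and most of the alveolar and mesothelial lists fell. Camera called none of these lists with an estimated correlation (smallest adjusted p 0.0574). Cxcl13, the chemokine that draws B cells and follicular helper T cells into lymphoid tissue (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068, mm10), rose from 3.35 ± 0.579 CPM (SD, n = 3) in young to 38.2 ± 18.5 in aged mice. Its log2 fold change was 3.51 ± 0.39 with an edgeR adjusted p of 0.000375. Its receptor Cxcr5 rose by 1.25 ± 0.22 (edgeR adjusted p 0.00299). Pdcd1, which encodes PD-1 itself, rose by 2.29 ± 0.51 (edgeR adjusted p 0.0109) from 1.10 ± 0.153 to 5.44 ± 4.31 CPM. Without the third young library Pdcd1 missed the call, at an edgeR adjusted p of 0.0516. The IL-21 receptor gene Il21r rose by 0.90 ± 0.22 (edgeR adjusted p 0.0160), a call that was lost without the third aged anti-PD-1 or the second young library (highest edgeR adjusted p 0.0769). The PD-1 ligand gene Cd274 was not called (0.55 ± 0.33, edgeR adjusted p 0.286).

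**Figure D1:**
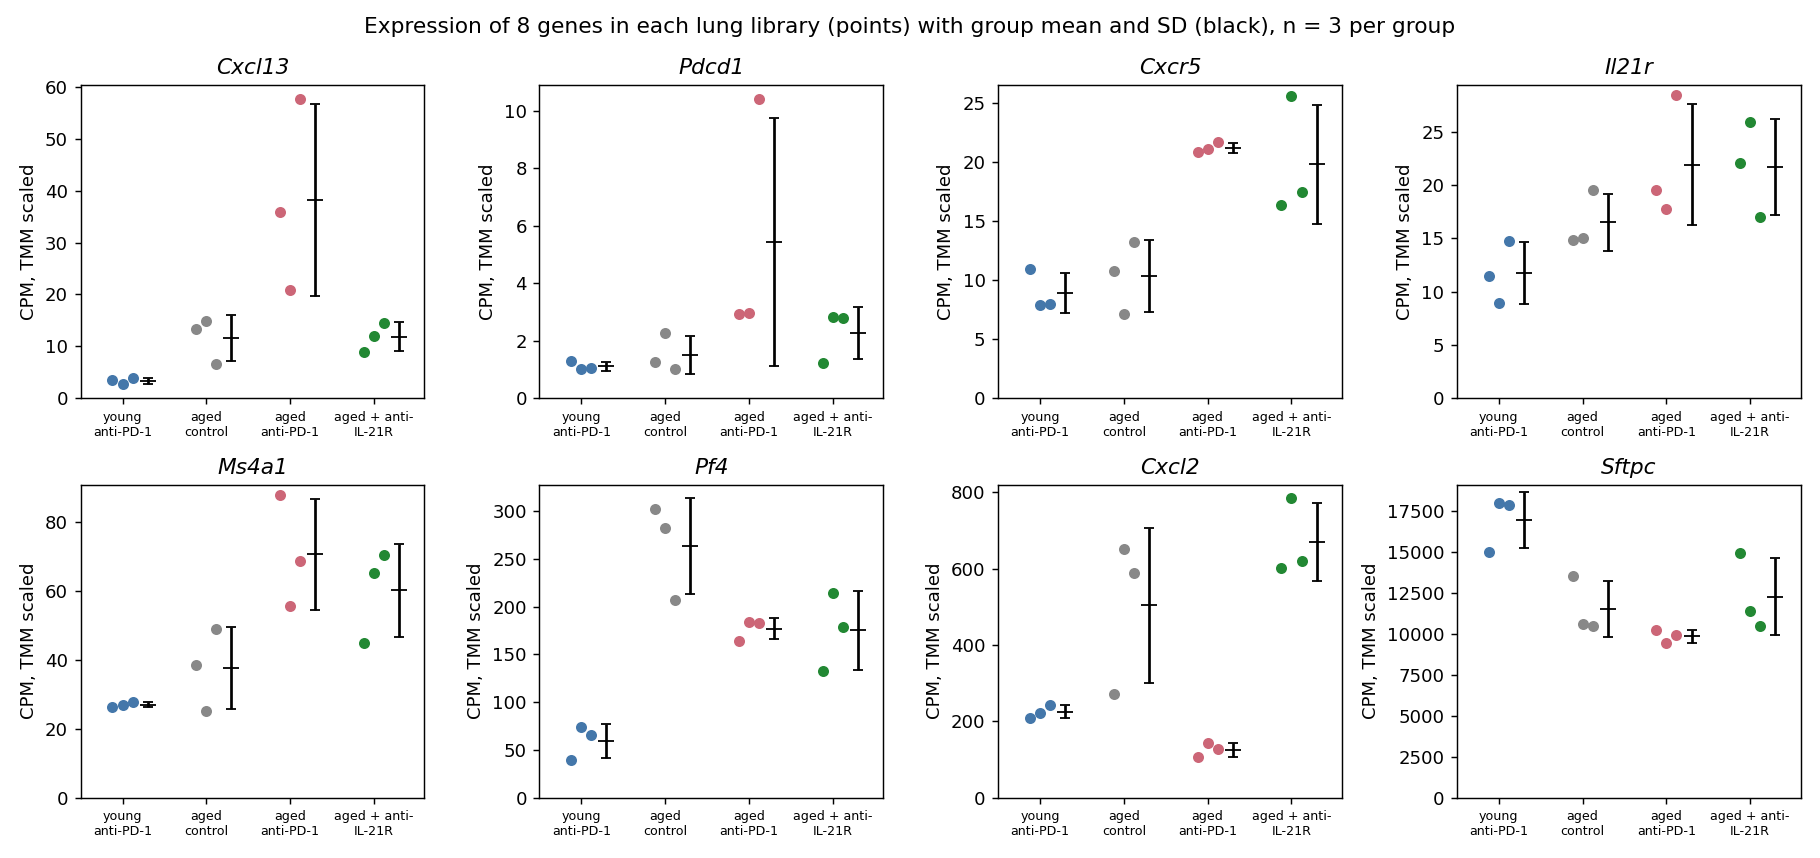
TMM-scaled CPM (linear y axis from 0) of 8 genes by group, with coloured points for the 12 single libraries and black marks for the group mean and SD (n = 3). Cxcl13 stood at a mean of 3.35 CPM in young anti-PD-1, 11.6 in aged control, 38.2 in aged anti-PD-1 and 11.8 in combination lungs, and Cxcl2 at 225, 504, 126 and 669 CPM.

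Antibody genes made up the steepest part of this age difference. Of 23 plasma cell and immunoglobulin constant genes, 17 rose and 1 fell over all genes tested, and 18 rose and 1 fell adjusted over the list alone (median log2 fold change 1.84, camera adjusted p 2.7e-15, adjusted p = 0.0815 with an estimated correlation). The heavy chain genes Ighg2c (5.86 ± 1.58), Ighg2b (5.29 ± 0.90), Ighg3 (4.92 ± 0.65), Ighg1 (4.29 ± 0.95) and Igha (3.34 ± 0.38) rose, as did Jchain, the joining chain of polymeric antibody (4.66 ± 0.59), and Pou2af1, a B cell coactivator (1.68 ± 0.18). The Ighg1 call was lost without any 1 of the 3 young libraries (highest edgeR adjusted p 0.0802), and that of Ighg2c without any of those or the second or the third aged anti-PD-1 library (highest edgeR adjusted p 0.136). Immunoglobulin variable segments, whose near-identical copies share reads and are uncertain one by one, had 66 of 120 members higher and 0 lower by the edgeR test (94 and 0 adjusted over the list alone, median 2.31, camera adjusted p 2.0e-35, adjusted p = 0.0815 with an estimated correlation). Among 16 B cell markers 13 rose (15 adjusted over the list alone), with a median of 0.89 (camera adjusted p 8.1e-14, adjusted p = 0.159 with an estimated correlation). They included the transcription factor Spib (1.45 ± 0.17), the inhibitory receptor Cd22 (1.16 ± 0.18) and Bank1, a B cell signalling scaffold (1.29 ± 0.21). All 11 tested MHC class II genes rose, also when adjusted over the list alone (median 0.84, camera adjusted p 3.3e-12, adjusted p = 0.0815 with an estimated correlation). Among them were the class II transactivator Ciita (1.39 ± 0.23) and H2-Aa (0.84 ± 0.16).

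Follicular helper T cell genes rose in 11 of 14 cases (12 adjusted over the list alone), with a median of 1.02 (camera adjusted p 2.1e-11, adjusted p = 0.0574 with an estimated correlation). Maf, a transcription factor of these cells, rose by 0.91 ± 0.14 and the surface receptor Slamf6 by 1.15 ± 0.19. Lymphoid tissue chemokine and stroma genes had 8 of 14 members higher and 3 lower (9 and 3 adjusted over the list alone, median 0.61, camera adjusted p 0.00020, adjusted p = 0.0574 with an estimated correlation). Ltb, a subunit of lymphotoxin, rose by 1.07 ± 0.17. The lists on B cells, follicular helper cells and lymphoid tissue were drawn up with the study's subject in mind, so their direction is not independent evidence. Il21 itself had too few counts to pass the filter: 0, 1 and 1 in the young, 1, 4 and 3 in the aged control, 15, 5 and 11 in the aged anti-PD-1 and 1, 0 and 2 in the combination libraries. Tested without the filter, over 31441 genes, Il21 was higher in aged than in young lungs (3.64 ± 1.00, edgeR adjusted p 0.0154). It was not called in that test with anti-PD-1 (1.68 ± 0.83, edgeR adjusted p 0.269), with added anti-IL-21R (-2.83 ± 0.96, edgeR adjusted p 0.0769) or between combination and control (-1.15 ± 1.09, edgeR adjusted p 0.907). General T cell markers rose in 8 of 18 cases (9 adjusted over the list alone, median 0.62, camera adjusted p 0.00012, adjusted p = 0.567 with an estimated correlation). Their median was 0.32 without the third aged anti-PD-1 library. Checkpoint genes rose in 5 of 10 (6 adjusted over the list alone, median 1.27, camera adjusted p 0.00012, adjusted p = 0.309 with an estimated correlation), among them Ctla4 (1.26 ± 0.22) and Lag3 (1.87 ± 0.37), both inhibitory receptors. In the interferon gamma response 4 of 23 genes rose (6 adjusted over the list alone, median 0.47, camera adjusted p 0.00016, adjusted p = 0.567 with an estimated correlation). That median was 0.22 without the third aged anti-PD-1 library. The list was led by the ubiquitin-like Ubd (5.60 ± 0.55) and the T cell chemokine Cxcl9 (4.33 ± 0.87), which lost its call without the second or the third young library (highest edgeR adjusted p 0.0560).

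Platelet and megakaryocyte genes were higher in aged lungs as a block. All 10 rose, also when adjusted over the list alone, with a median of 1.82 (camera adjusted p 1.7e-27, adjusted p = 0.0574 with an estimated correlation). The collagen receptor Gp6 (1.88 ± 0.22) and the platelet chemokine Ppbp (1.65 ± 0.20) were among them. Pf4, platelet factor 4, a gene chosen after its values were seen, stood at 59.5 ± 18.1 CPM in young against 177 ± 11.2 in aged anti-PD-1 and 264 ± 50.2 in aged control lungs (SD, n = 3). Erythroid genes did not move with them (0 of 10 higher, 1 lower, median -0.20, camera adjusted p 0.66). Of 18 monocyte and interstitial macrophage genes 4 rose (11 adjusted over the list alone, median 0.63, camera adjusted p 6.1e-07, adjusted p = 0.211 with an estimated correlation), including the scavenger receptor Cd163 (1.82 ± 0.26). Among senescence and ageing genes 6 of 15 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p 0.59). The cell cycle inhibitor Cdkn2a rose by 2.05 ± 0.41 and the macrophage elastase Mmp12 by 1.52 ± 0.25, whereas Cdkn2b, its neighbour, fell by 1.39 ± 0.25. Rgs5, a pericyte regulator of G protein signalling, had the smallest edgeR adjusted p of this comparison (1.8e-05) and rose from 6.09 ± 0.242 to 28.2 ± 0.813 CPM.

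Among the structural lists, some had called members that fell and others members that rose. Of 14 type 2 alveolar genes 13 fell, also when adjusted over the list alone (median -0.70, camera adjusted p 9.5e-12, adjusted p = 0.106 with an estimated correlation). Among them the surfactant lipid transporter Abca3 fell by 0.75 ± 0.14 and Lamp3, a lamellar body protein, fell by 1.01 ± 0.17. Type 1 alveolar genes fell in 9 of 12 cases (10 adjusted over the list alone, median -0.86, camera adjusted p 1.9e-07, adjusted p = 0.333 with an estimated correlation). Mesothelial genes fell in 7 of 8 (7 adjusted over the list alone, median -1.37, camera adjusted p 1.2e-09, adjusted p = 0.0815 with an estimated correlation), and mesothelin, Msln, went down from 139 ± 39.3 to 45.6 ± 5.80 CPM. Secretory airway genes fell in 4 of 13 (8 adjusted over the list alone, median -0.71, camera adjusted p 2.0e-05, adjusted p = 0.409 with an estimated correlation). Fibroblast and collagen genes fell in 9 of 25 (9 adjusted over the list alone, median -0.47, camera adjusted p 3.1e-06, adjusted p = 0.368 with an estimated correlation). The fibroblast median was -0.74 without the first aged anti-PD-1 library. The cornified envelope genes Sprr1a (fell by 4.38 ± 0.47) and Ivl (fell by 3.44 ± 0.60) led the lower genes that the naming rule picks by fold change. Lymphatic endothelial genes had 6 of 7 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.84, camera adjusted p 8.7e-06, adjusted p = 0.0574 with an estimated correlation). Blood endothelial genes rose in 2 of 16 (2 adjusted over the list alone, median 0.36, camera adjusted p 0.020, adjusted p = 0.664 with an estimated correlation), a call lost without the second aged anti-PD-1 (camera adjusted p 0.083) or the second young library (camera adjusted p 0.066). Cardiac muscle genes rose in 4 of 12 (4 adjusted over the list alone, median 0.25, camera adjusted p 0.018, adjusted p = 0.660 with an estimated correlation). That call was lost without the second aged anti-PD-1 library (median 0.0105, camera adjusted p 0.215) or the third young library (camera adjusted p 0.093), and the median was 0.42 without the third aged anti-PD-1 library.

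In all, 2830 genes were called in this comparison, 1502 higher and 1328 lower in aged lungs, of which 522 and 312 changed at least 2-fold. The ranges of the 3 and 3 libraries did not overlap for 39.6% of the genes tested, where chance gives 10%. Camera called 30 of 50 lists and fry 19, and with an estimated correlation camera called 0 (smallest adjusted p 0.0574). Other groupings of the same 6 libraries called 12 to 30 lists. Mitochondrially encoded genes were among the lists called (8 of 23 higher, 11 adjusted over the list alone, median 0.69, camera adjusted p 1.8e-07, adjusted p = 0.409 with an estimated correlation), with a median of 0.45 without the third aged anti-PD-1 library. Glucocorticoid response genes were called too (7 of 13 higher and 1 lower, 7 and 2 adjusted over the list alone, median 0.48, camera adjusted p 0.0012, adjusted p = 0.159 with an estimated correlation). Clock genes went both ways, with 4 of 16 higher and 4 lower. With the clock score as a covariate 65 genes were called, 57 higher and 8 lower. The count of called genes was 1160 without the third young library, 1404 without the second young library and 1252 without the third aged anti-PD-1 library. No young control group was measured, so whether age changes the response to anti-PD-1 could not be tested.

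**Figure D2:**
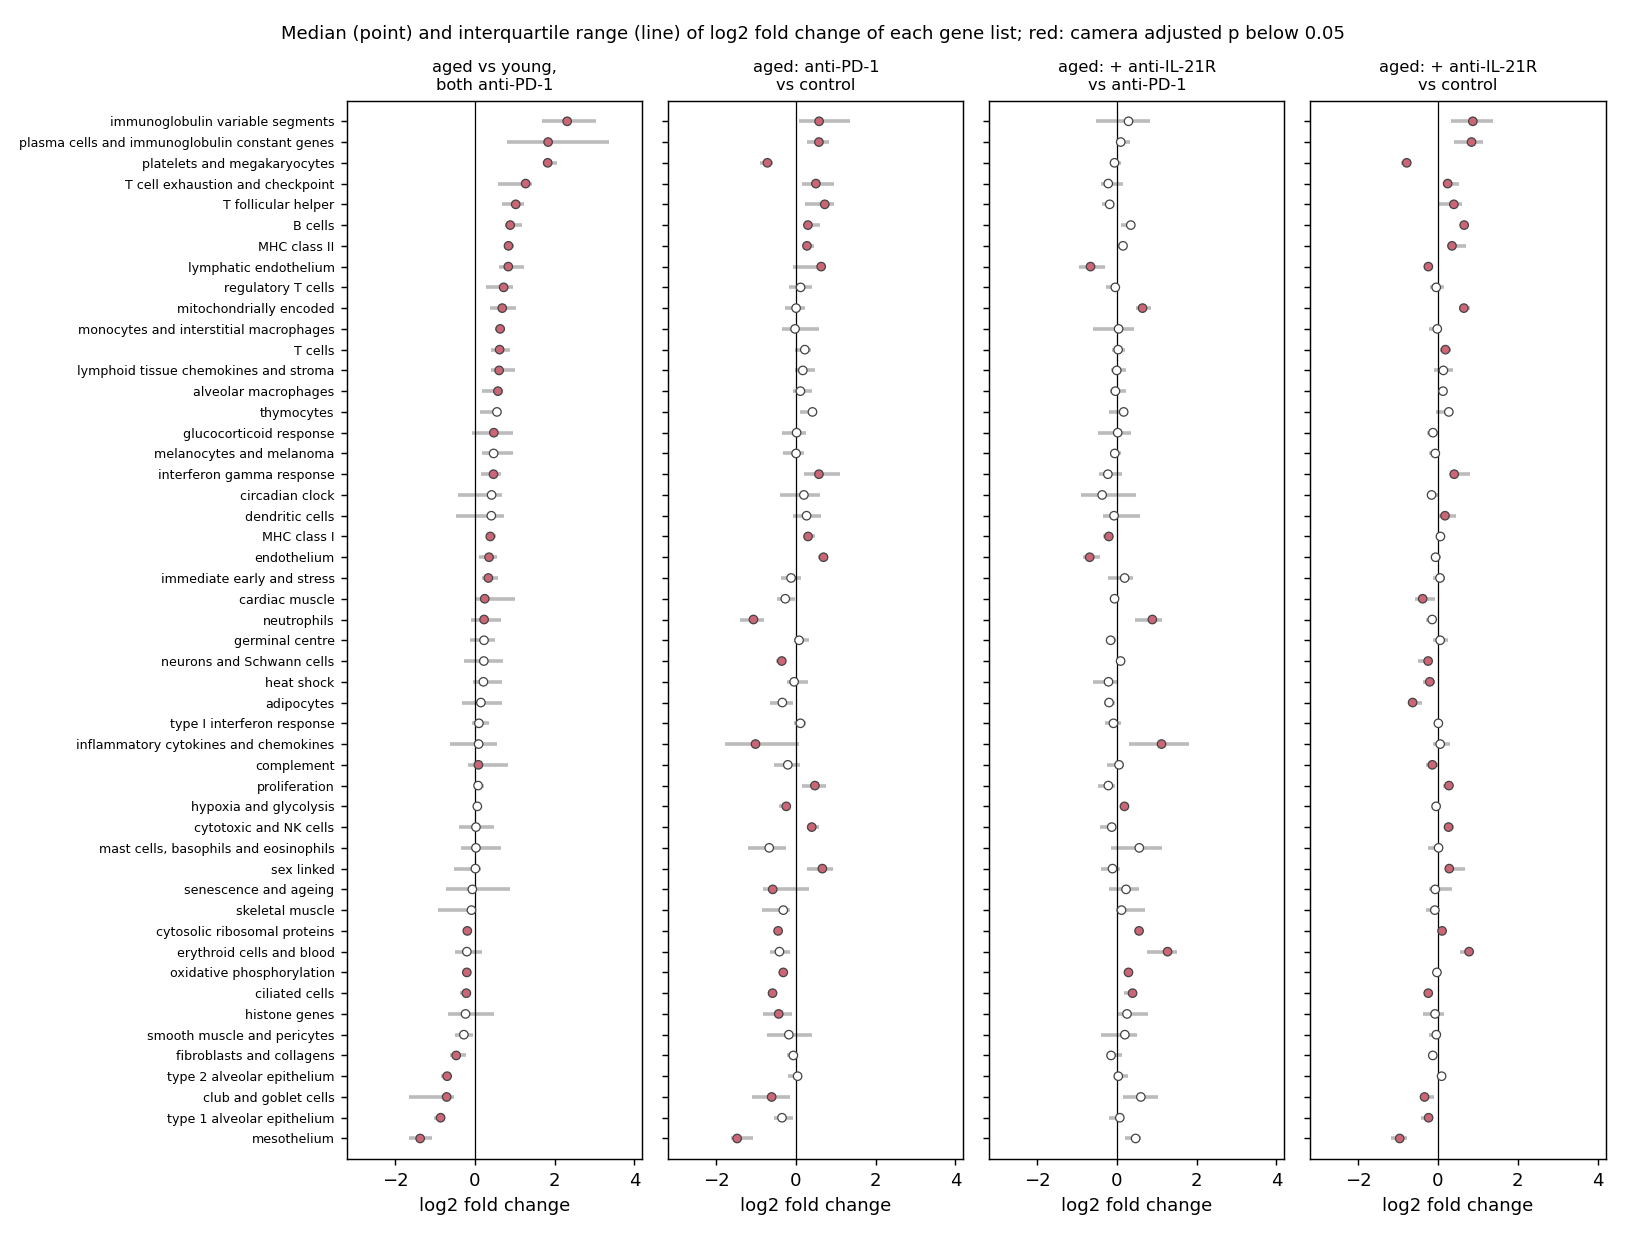
Median log2 fold change (points) with the interquartile range of members (bars) of the 50 gene lists in the 4 comparisons, in red where camera with a preset correlation of 0.01 gave an adjusted p under 0.05. Platelet genes had a median of 1.82 in aged against young anti-PD-1 lungs, and ribosomal protein genes a median of -0.45 with anti-PD-1 and 0.55 with added anti-IL-21R.

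The next comparison, aged anti-PD-1 against aged control lungs, asked what the antibody changed in aged mice. Camera at its preset correlation called lists in both directions, while with an estimated correlation it called none (smallest adjusted p 0.358), and in each list described here at most a part of the members passed over all genes. Cxcl13 rose from 11.6 ± 4.41 to 38.2 ± 18.5 CPM (SD, n = 3), by 1.72 ± 0.35 with an edgeR adjusted p of 0.0136. Cxcr5 rose from 10.4 ± 3.06 to 21.2 ± 0.416 CPM, by 1.03 ± 0.22 with an edgeR adjusted p of 0.0133. Both stayed called in each fit that left out 1 library. Pdcd1 rose by 1.85 ± 0.50 (edgeR adjusted p 0.0345), but was called in only some of those fits. Without the third aged anti-PD-1 library or any 1 of the 3 control libraries it was lost, with an edgeR adjusted p of up to 0.154. Il21r (0.41 ± 0.22, edgeR adjusted p 0.232) and Cd274 (0.13 ± 0.32, edgeR adjusted p 0.831) were not called.

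Follicular helper genes rose in 6 of 14 cases with 0 lower (9 higher and 1 lower adjusted over the list alone), with a median of 0.72 (camera adjusted p 5.1e-06, adjusted p = 0.358 with an estimated correlation). Tox2, a nuclear factor of these cells, rose by 0.98 ± 0.18 and Slamf6 by 0.96 ± 0.18. B cell markers rose in 4 of 16 (5 adjusted over the list alone, median 0.30, camera adjusted p 0.00049, adjusted p = 0.505 with an estimated correlation). Among them Ms4a1, which encodes CD20, rose by 0.91 ± 0.23, a call lost without the first or the third aged anti-PD-1 or the first or second control library (highest edgeR adjusted p 0.0870). The B cell median was 0.10 without the second control library. In the plasma cell list Pou2af1 (0.89 ± 0.17) and Ighg3 (1.85 ± 0.50) were the 2 of 23 that rose (2 adjusted over the list alone, median 0.58, camera adjusted p 0.00081, adjusted p = 0.483 with an estimated correlation). The plasma cell median was 0.33 without the third aged anti-PD-1, 0.88 without the first control and 0.30 without the second control library. The Ighg3 call was lost without the second or the third library of either group (highest edgeR adjusted p 0.132). Variable segments rose in 15 of 120 (15 adjusted over the list alone, median 0.58, camera adjusted p 8.7e-06, adjusted p = 0.505 with an estimated correlation), with a median of 0.17 without the third aged anti-PD-1 library. Interferon gamma response genes rose in 7 of 23 (9 adjusted over the list alone, median 0.58, camera adjusted p 6.0e-05, adjusted p = 0.505 with an estimated correlation). Ubd rose by 2.22 ± 0.40, Ciita by 1.24 ± 0.23 and Cxcl9 by 3.54 ± 0.82. The Cxcl9 counts of the 3 aged anti-PD-1 libraries were uneven, at 479, 278 and 2416, and without any 1 of the 3 control libraries its call was lost (highest edgeR adjusted p 0.0972). Checkpoint genes rose in 3 of 10 (3 adjusted over the list alone, median 0.50, camera adjusted p 0.023, adjusted p = 0.505 with an estimated correlation). Cytotoxic and NK cell genes had 0 of 18 called (0 adjusted over the list alone, median 0.40, camera adjusted p 0.012, adjusted p = 0.672 with an estimated correlation). Both calls were lost without the third aged anti-PD-1 library (medians 0.21 and 0.20) or the first control library (medians 0.27 and 0.25), and the cytotoxic median was 0.79 without the second control library. Class II genes rose in 2 of 11 (3 adjusted over the list alone, median 0.28, camera adjusted p 0.0013, adjusted p = 0.483 with an estimated correlation), with a median of 0.42 without the first aged anti-PD-1 library. Class I genes had 0 of 14 called (0 adjusted over the list alone, median 0.30, camera adjusted p 0.0024, adjusted p = 0.617 with an estimated correlation). Without the third aged anti-PD-1 library both class lists lost their call (medians 0.12 and 0.18). Proliferation genes rose in 1 of 22 (10 adjusted over the list alone, median 0.48, camera adjusted p 0.00018, adjusted p = 0.483 with an estimated correlation), with a median of 0.31 without the third aged anti-PD-1 and 0.74 without the second control library. Several related lists were not called: type I interferon genes (1 of 22 higher, median 0.11, camera adjusted p 0.34), T cell markers (0 of 18, median 0.22, camera adjusted p 0.41), and lymphoid tissue chemokines and stroma (4 of 14 higher and 2 lower, median 0.17, camera adjusted p 0.16). The same held for regulatory T cells (1 of 9 higher, median 0.12, camera adjusted p 0.42) and germinal centre genes (1 of 8 lower, median 0.08, camera adjusted p 0.88).

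Part of the cytokine and neutrophil lists fell with anti-PD-1, while the list of monocytes and interstitial macrophages was not called (4 of 18 higher and 1 lower, median -0.0216, camera adjusted p 0.42). Of 20 inflammatory cytokines and chemokines 7 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -1.01 (camera adjusted p 1.1e-06, adjusted p = 0.390 with an estimated correlation). The neutrophil chemokine Cxcl1 fell by 2.27 ± 0.24 (edgeR adjusted p 0.00127), Cxcl2 fell by 2.00 ± 0.26 from 504 ± 203 to 126 ± 17.8 CPM, and Ccl2, a monocyte chemokine, fell by 1.79 ± 0.21. The members that rose were Ccl8 (2.29 ± 0.52) and Ccl12 (1.40 ± 0.26), also monocyte chemokines; that of Ccl8 was lost without the third aged anti-PD-1 or the second or the third control library (highest edgeR adjusted p 0.0882). Neutrophil genes fell in 8 of 16 (8 adjusted over the list alone, median -1.06, camera adjusted p 4.1e-09, adjusted p = 0.390 with an estimated correlation), with a median of -0.71 without the second control library. S100a9, a subunit of calprotectin, fell by 1.40 ± 0.21 from 863 ± 142 to 326 ± 58.3 CPM. The AP-1 factor Fosl1 fell by 2.42 ± 0.30. The metallothionein Mt1 fell by 1.22 ± 0.23; the list of glucocorticoid response genes that holds it was not called (camera adjusted p 0.21). Hypoxia and glycolysis genes fell in 5 of 17 (6 adjusted over the list alone, median -0.24, camera adjusted p 0.00022, adjusted p = 0.358 with an estimated correlation), and the median was -0.14 with library totals alone. The glucose transporter Slc2a1 fell by 0.64 ± 0.12.

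Endothelial genes rose in 8 of 16 cases (12 adjusted over the list alone, median 0.69, camera adjusted p 3.4e-09, adjusted p = 0.390 with an estimated correlation). Pecam1, an endothelial adhesion molecule, rose by 0.73 ± 0.14 and the VEGF receptor Flt1 by 0.72 ± 0.14. In the lymphatic list 3 of 7 rose (4 adjusted over the list alone, median 0.63, camera adjusted p 0.010, adjusted p = 0.385 with an estimated correlation). The hyaluronan receptor Lyve1 rose by 0.83 ± 0.12. Mesothelial genes fell in 7 of 8 (8 adjusted over the list alone, median -1.47, camera adjusted p 4.0e-09, adjusted p = 0.358 with an estimated correlation). Msln fell by 1.42 ± 0.20. Ciliated cell genes fell in 8 of 14 (12 adjusted over the list alone, median -0.59, camera adjusted p 5.4e-09, adjusted p = 0.390 with an estimated correlation). Ribosomal protein genes fell in 34 of 81 cases (72 adjusted over the list alone, median -0.45, camera adjusted p 6.9e-22, adjusted p = 0.469 with an estimated correlation). Nuclear genes of the respiratory chain fell in 14 of 79 (43 adjusted over the list alone, median -0.32, camera adjusted p 3.4e-12, adjusted p = 0.498 with an estimated correlation), with a median of -0.21 without the first control library and also with library totals alone. Platelet genes fell in 3 of 10 (8 adjusted over the list alone, median -0.71, camera adjusted p 1.3e-05, adjusted p = 0.481 with an estimated correlation). Sex-linked genes rose in 2 of 6 (2 adjusted over the list alone, median 0.66, camera adjusted p 0.0023, adjusted p = 0.358 with an estimated correlation). These were the Y-linked demethylase genes Kdm5d (0.81 ± 0.13) and Uty (0.98 ± 0.18), while the Y-linked helicase gene Ddx3y, chosen after its values were seen, was not called (0.21 ± 0.12, edgeR adjusted p 0.253). Alb, a liver transcript that can mark carry-over from other tissue, rose by 3.29 ± 0.82 with 13, 67 and 148 counts in the aged anti-PD-1 libraries, and its call was lost in 5 of the 6 fits without 1 library (highest edgeR adjusted p 0.0992).

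Anti-PD-1 in aged mice gave 2025 called genes, 990 higher and 1035 lower, with 160 and 182 changed at least 2-fold. Scaled by library totals alone, 1400 were higher and 559 lower, and the median of all genes then moved to 0.09. The count was 51 with the clock score as a covariate, 881 with only the 2 groups compared, and 1175 with the length and GC content trend removed and replicate number as a block. The ranges of the libraries did not overlap for 32.5% of genes (chance 10%). Camera called 25 of 50 lists and fry 14, and 0 with an estimated correlation (smallest adjusted p 0.358); other groupings of the same 6 libraries called 14 to 28. The count of genes was 607 without the second control library, and 1057, 881 and 715 without the first, second and the third aged anti-PD-1 library.

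Adding the IL-21 receptor antibody was examined by comparing the combination with the aged anti-PD-1 group. Camera called lists in both directions at its preset correlation and none with an estimated one (smallest adjusted p 0.185). Cxcl13 fell from 38.2 ± 18.5 to 11.8 ± 2.82 CPM (SD, n = 3), by 1.70 ± 0.35 with an edgeR adjusted p of 0.0157, and missed the call without the second combination library (edgeR adjusted p 0.0709). Cxcr5 was not called (-0.10 ± 0.21, edgeR adjusted p 0.802; 19.8 ± 5.07 CPM in the combination group), and neither were Pdcd1 (-1.26 ± 0.49, edgeR adjusted p 0.118), Cd274 (0.20 ± 0.32, edgeR adjusted p 0.736) or Il21r (-0.01 ± 0.22, edgeR adjusted p 0.978).

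Lymphoid lists were not called here. The B cell list had a median of 0.35 (1 of 16 higher, camera adjusted p 0.059), the plasma cell list 0.09 (0 of 23, camera adjusted p 0.53) and the follicular helper list -0.18 (1 of 14 lower, camera adjusted p 0.084). The member that fell there was Cd200, an inhibitory surface ligand, by 0.60 ± 0.12. The interferon gamma list had 0 of 23 members called (median -0.23, camera adjusted p 0.40), with Ubd at -1.01 ± 0.37 and Cxcl9 at -2.23 ± 0.76, both uncalled.

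Of 20 inflammatory cytokines and chemokines 8 rose and 2 fell (11 and 2 adjusted over the list alone, median 1.12, camera adjusted p 1.9e-09, adjusted p = 0.482 with an estimated correlation). Cxcl2 rose from 126 ± 17.8 to 669 ± 102 CPM, by 2.41 ± 0.26 with an edgeR adjusted p of 0.00108. Cxcl3 (2.61 ± 0.40), Cxcl1 (2.03 ± 0.24) and Ccl2 (1.77 ± 0.21) rose with it, while Ccl8 fell by 1.88 ± 0.52. The Ccl8 call was lost without any 1 of the 3 combination libraries or the first or the third aged anti-PD-1 library (highest edgeR adjusted p 0.122). Neutrophil genes rose in 8 of 16 (8 adjusted over the list alone, median 0.89, camera adjusted p 1.6e-08, adjusted p = 0.548 with an estimated correlation). S100a9 rose by 1.34 ± 0.21 and the decoy receptor Il1r2 by 1.70 ± 0.24. Hypoxia and glycolysis genes rose in 3 of 17 (4 adjusted over the list alone, median 0.19, camera adjusted p 0.0012, adjusted p = 0.482 with an estimated correlation). With library totals alone the hypoxia median was -0.00694. Endothelial genes fell in 9 of 16 (14 adjusted over the list alone, median -0.68, camera adjusted p 1.8e-10, adjusted p = 0.545 with an estimated correlation). Lymphatic genes fell in 4 of 7 (5 adjusted over the list alone, median -0.66, camera adjusted p 9.8e-06, adjusted p = 0.185 with an estimated correlation). Pecam1 fell by 0.81 ± 0.14, and Lyve1 fell by 1.17 ± 0.12 from 271 ± 21.8 to 120 ± 17.2 CPM. Cd163 fell by 1.61 ± 0.26 and the folate receptor Folr2 by 1.58 ± 0.27, both markers of resident macrophages whose list was not called (camera adjusted p 0.20).

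Signs of library make-up moved with this comparison. Ribosomal protein genes rose in 58 of 81 cases (72 adjusted over the list alone, median 0.55, camera adjusted p 1.3e-36, adjusted p = 0.545 with an estimated correlation), with a median of 0.35 with library totals alone. Respiratory chain genes rose in 11 of 79 (33 adjusted over the list alone, median 0.29, camera adjusted p 2.4e-11, adjusted p = 0.902 with an estimated correlation), with a median of 0.19 without the second combination library and 0.0876 with library totals alone. Mitochondrially encoded genes rose in 7 of 23 (12 adjusted over the list alone, median 0.64, camera adjusted p 1.3e-08, adjusted p = 0.548 with an estimated correlation). Erythroid genes rose in 5 of 10 (8 adjusted over the list alone, median 1.27, camera adjusted p 2.6e-07, adjusted p = 0.482 with an estimated correlation). The haemoglobin gene Hba-a1 rose by 1.39 ± 0.27, a call lost without the second combination library (edgeR adjusted p 0.0509). Ciliated cell genes rose in 3 of 14 (7 adjusted over the list alone, median 0.39, camera adjusted p 0.00024, adjusted p = 0.902 with an estimated correlation), with a median of 0.18 with library totals alone. Among the genes that the naming rule picks by fold change, the largest rises were those of 2 non-coding RNAs. These were Rn7sk (3.70 ± 0.61) and the ribosomal RNA repeat Rn18s-rs5 (2.68 ± 0.52), which poly(A) selection should largely remove. The Rn18s-rs5 call was lost without the second combination or any 1 of the 3 aged anti-PD-1 libraries (highest edgeR adjusted p 0.0630).

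Between combination and aged anti-PD-1 lungs 1674 genes were called, 866 higher and 808 lower, and 150 and 133 changed at least 2-fold. With library totals alone 361 were higher and 2677 lower, and the median of all genes moved to -0.21. The count was 110 with the clock score as a covariate and 2536 with DESeq2. For 32.2% of genes the libraries did not overlap (chance 10%). Camera called 11 of 50 lists and fry 4, and 0 with an estimated correlation (smallest adjusted p 0.185); other groupings of the same 6 libraries called 10 to 26. Without the second combination library 260 genes were called, and without the first, second or the third aged anti-PD-1 library 584, 641 and 954.

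The last comparison set the combination against the aged control group, to show how lungs given both antibodies differed from control. No single gene was called: edgeR found 0 genes, with 1228 at an unadjusted p under 0.05 and a smallest adjusted p of 0.245, DESeq2 found 74 and limma-voom 0. Without the count filter 11 were called, and 1 with the length and GC content trend removed. Cxcl13 was at 11.8 ± 2.82 CPM against 11.6 ± 4.41 in controls (SD, n = 3; 0.02 ± 0.36, edgeR adjusted p 0.996). Cxcr5 (0.93 ± 0.22, edgeR adjusted p 0.348), Pdcd1 (0.59 ± 0.53, edgeR adjusted p 0.921), Il21r (0.40 ± 0.22, edgeR adjusted p 0.816) and Cd274 (0.33 ± 0.32, edgeR adjusted p 0.935) were uncalled. The smallest p-values belonged to the integrin Itga6 (-0.63 ± 0.10), the segment Igkv2-109 (2.37 ± 0.42), the BAFF receptor Tnfrsf13c (1.14 ± 0.20), the thrombin receptor F2rl2 (-0.80 ± 0.15) and Ptgs1, cyclooxygenase of platelets among other cells (-0.46 ± 0.09). Ranges did not overlap for 9.71% of genes, where chance gives 10%.

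As sets, several lists stood apart by camera, each with 0 members called over all genes. Of the 26 lists called, 15 lost their call without at least 1 library, and other groupings of the same 6 libraries called 10 to 25 lists. B cell markers had a median of 0.66 (14 of 16 higher adjusted over the list alone, camera adjusted p 1.1e-25, adjusted p = 0.0970 with an estimated correlation). Class II genes had a median of 0.35 (6 of 11 higher, camera adjusted p 5.7e-15, adjusted p = 0.0970 with an estimated correlation) and plasma cell genes 0.84 (7 of 23 higher, camera adjusted p 1.3e-14, adjusted p = 0.0970 with an estimated correlation). Mitochondrially encoded genes had a median of 0.65 (12 of 23 higher, camera adjusted p 2.0e-23, adjusted p = 0.0970 with an estimated correlation) and erythroid genes 0.78 (3 of 10 higher, camera adjusted p 1.6e-08, adjusted p = 0.128 with an estimated correlation), the latter at 0.42 without the second combination library. With anti-PD-1 alone against control these 2 lists were not called (median 0.00484, camera adjusted p 0.98, and median -0.41, camera adjusted p 0.076). Platelet genes were at a median of -0.78 (10 of 10 lower adjusted over the list alone, camera adjusted p 3.5e-20, adjusted p = 0.0970 with an estimated correlation) and mesothelial genes at -0.96 (8 of 8 lower, camera adjusted p 2.2e-13, adjusted p = 0.0970 with an estimated correlation). Neutrophil genes (median -0.14, camera adjusted p 0.45), inflammatory chemokines (median 0.06, camera adjusted p 0.14) and endothelial genes (median -0.06, camera adjusted p 0.79) were not called. Camera called 26 lists in all and 0 with an estimated correlation (smallest adjusted p 0.0970), and fry called 0. Without the first combination library edgeR called 13 genes.

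Gene by gene, the anti-PD-1 and the combination comparisons mirrored each other. Of the genes that rose with anti-PD-1, 513 fell in the combination group, where 43.1 would overlap if the lists were independent. Of those that fell, 551 rose (48.3 if independent). Cxcl13, Pecam1 and Lyve1 belonged to the first set, and Cxcl1, Cxcl2, Ccl2 and S100a9 to the second. Across genes, which are not independent replicates, the log2 fold changes of the comparisons had a correlation of -0.741 and a covariance of -0.169. Both use the same 3 aged anti-PD-1 libraries with opposite sign. Simulated groups with no effect gave a correlation of -0.486 and a covariance of -0.0401 (mean of 100 simulations). Either simulated overlap held at most 1 gene. The simulations called at most 1 gene with anti-PD-1 and 2 with added anti-IL-21R, so these overlaps are no reference for the real ones. The shared group of 3 cannot be split with 2 libraries on each side, so part of the excess may come from the shared libraries. With library totals alone the overlaps were 1141 and 229, and with the clock score as a covariate 18 and 19. They were 120 and 116 genes without the second combination library, and 209 and 214 without the second control library. Without the first, second or the third aged anti-PD-1 library the first overlap held 208, 201 and 225 genes and the second 183, 207 and 221. Age and anti-PD-1 shared 437 higher genes (80.1 if independent) and 345 lower ones (74.1 if independent), with a covariance of 0.156 against 0.0399 in the simulations and a correlation of 0.535 against 0.492. These overlaps were 130 and 86 without the third and 226 and 132 without the second aged anti-PD-1 library, 205 and 190 without the second and 205 and 136 without the third young library, and 200 and 145 without the second control library. Without the first aged anti-PD-1 library the higher set held 262 genes. With the clock score as a covariate the sets held 10 and 3 genes, and with library totals alone the lower set held 172.

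**Figure D3:**
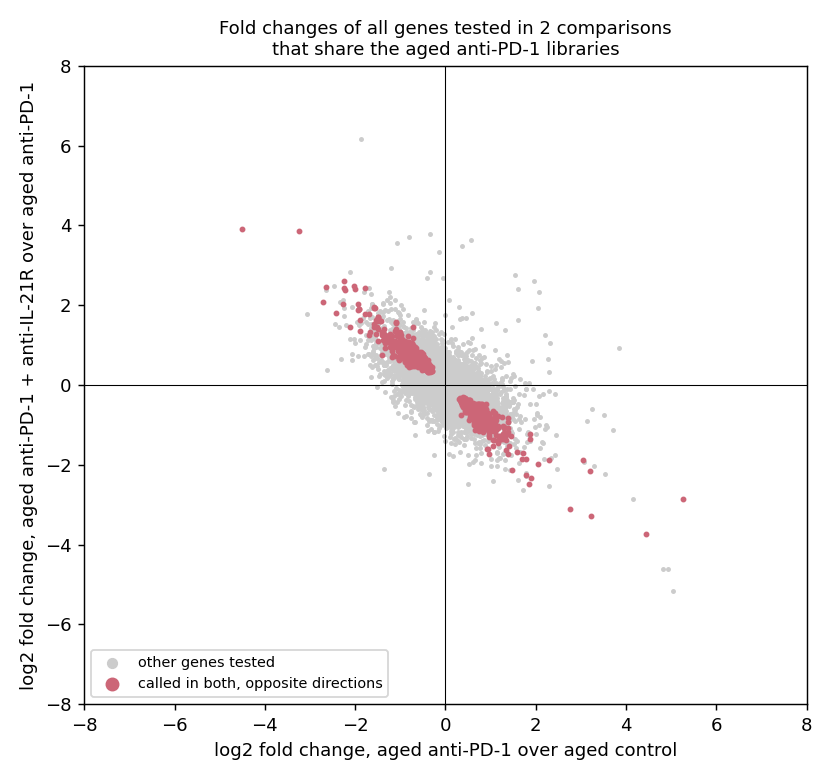
Log2 fold change with anti-PD-1 (aged anti-PD-1 against aged control, x axis) and with added anti-IL-21R (combination against aged anti-PD-1, y axis), 1 point per gene, in red for genes called in both in opposite directions. The points lie along the falling diagonal, with a correlation across genes of -0.741 where simulated groups with no effect gave -0.486.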

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

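Removal of the length and GC content trend and the clock score covariate were chosen only after the results were seen; the other alternatives were planned. Of the values for named genes under all alternatives, 8370 kept direction and side of the threshold, 1388 lost the call, 90 gained one and 22 moved. For the lists 3051 were unchanged, 225 lost the call, 117 gained one, 187 medians changed sign with no call before or after, and 20 reversed with a call. The counts of genes changed at least 2-fold stayed within 1.5 times in 58 cases and moved further in 14. DESeq2 and limma-voom were not run on lists. The cause was not tested for any change below unless stated.

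Called genes for aged against young anti-PD-1 fell outside 1.5 times the reported count only with the clock score covariate (65) among the alternatives that keep all libraries. For anti-PD-1 against control the count was 1175 with the length and GC trend removed and a replicate block, 51 with the clock score and 881 with only the 2 groups compared. The last leaves fewer libraries to estimate the spread, but it did not always lower the count: aged against young had 3742 called genes under it, against 2830 as reported. For combination against anti-PD-1 it was 2536 with DESeq2, 3038 with library totals alone and 110 with the clock score, and for combination against control 74 with DESeq2, 11 with no low count filter and 1 with the length and GC trend removed. The clock score differs between groups, so as a covariate it also takes up group differences: groups account for 66.9% of its variance.

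With an estimated correlation camera called 0 lists in each comparison, and fry called 19, 14, 4 and 0 in the order of the report. For combination against anti-PD-1 camera called 18 lists with library totals alone and 17 with the clock score.

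Genes raised by anti-PD-1 and lowered in the combination numbered 816 with DESeq2, 1141 with library totals alone, 323 with the length and GC trend removed and a replicate block, 18 with the clock score and 302 with only the 2 groups compared. The mirror set numbered 881, 229, 344, 19 and 234 under the same alternatives. Genes higher with age and with anti-PD-1 numbered 10 with the clock score. Those lower with both numbered 172 with library totals alone, 203 with the length and GC trend removed and a replicate block, 3 with the clock score and 175 with only the 2 groups compared.

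Leaving out 1 library gave 1160 to 2237 called genes for aged against young, 607 to 1995 for anti-PD-1 against control, 260 to 1439 for combination against anti-PD-1 and 0 to 13 for combination against control. Called lists ranged from 27 to 29, 21 to 30, 11 to 18 and 23 to 31, but not always with the same lists: 9 of 30, 7 of 25, 1 of 11 and 15 of 26 lost their call without at least 1 library. The overlaps ranged from 120 to 618 (raised, then lowered), 116 to 645 (lowered, then raised), 130 to 394 (higher with both) and 86 to 315 (lower with both). Fewer libraries give less power, which tends to lower the counts, but fits with equally many libraries also differed. Combination against anti-PD-1 gave 260 genes without the second and 1439 without the first combination library. Some counts rose: the mirrored overlaps were 618 and 645 without the first control library, against 513 and 551 with all libraries.

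List medians changed sign with a call before or after in these cases. With the clock score, cardiac muscle went to -0.13 and senescence to 0.33 in aged against young, fibroblasts and collagens to 0.20 and heat shock to 0.22 with anti-PD-1, and monocytes and interstitial macrophages to -0.11 in combination against anti-PD-1. With library totals alone, hypoxia and glycolysis went to -0.00694 in combination against anti-PD-1 and inflammatory cytokines and chemokines to -0.0401 in combination against control. When 1 library was left out, medians with anti-PD-1 ranged from -0.13 to 0.11 for glucocorticoid response and from -0.22 to 0.19 for mitochondrially encoded genes, and in combination against anti-PD-1 from -0.17 to 0.15 for monocytes and interstitial macrophages. In combination against control they ranged from -0.483 to 0.0141 for type 1 alveolar epithelium, -0.25 to 0.19 for endothelium, -0.14 to 0.20 for immediate early genes, -0.110 to 0.0710 for oxidative phosphorylation, -0.36 to 0.21 for neutrophils, -0.14 to 0.18 for type I interferon response, -0.502 to 0.0187 for club and goblet cells and -0.0163 to 0.180 for cytosolic ribosomal proteins.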

Other observations

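The length and GC content test of the mirrored changes, the slope over clock genes outside the score, the clock score covariate, the tests on platelet and ribosomal protein genes and the process terms named here were chosen only after the results were seen.

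Of 1580 biological process terms, camera called 96, 38, 34 and 60 in the order of the comparisons, and 0 with an estimated correlation (smallest adjusted p 0.360, 0.977, 0.896 and 0.259). In aged against young lungs the term bicellular tight junction assembly had 16 of 42 genes lower (median -0.39, camera adjusted p 0.000438, adjusted p = 0.927 with an estimated correlation), among them the adhesion gene Cdh1 (fell by 0.87 ± 0.17) and the occludin gene Ocln (fell by 0.95 ± 0.20). In combination against aged anti-PD-1 lungs the semaphorin-plexin signalling term had 9 of 36 genes lower and 1 higher (median -0.31, camera adjusted p 0.000674, adjusted p = 0.896 with an estimated correlation), and its guidance gene Sema6d fell by 1.07 ± 0.13.

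Genes raised by anti-PD-1 in aged lungs were lower in the combination group, and the reverse. These mirrored changes were weighed against 3 technical explanations. Noise drawn for each gene independently is argued against by a covariance of fold changes of -0.169, beyond the lowest of 100 simulated values, -0.0434. Noise common to many genes of a library was not simulated, so noise of the shared aged anti-PD-1 libraries stays open. A length and GC content trend as the whole cause is argued against because 591 of 1064 genes were still called in opposite directions with the trend removed. The case is weaker with replicate number as a block as well, where 268 of 513 and 263 of 551 stayed called. The block without the trend removal kept 412 and 420. An hour of collection that differs between groups stays open. Fold changes predicted from the clock score within groups had a slope of -0.0358 on the observed ones (SD 0.0427 with scores permuted within groups), under the 0.5 set beforehand as the bound against this explanation. That bound was wrong: 8 clock genes outside the score gave only 0.461 (SD 0.348), not apart from 0, so a low slope excludes nothing. The slope also rests mainly on the aged anti-PD-1 libraries, whose scores had an SD of 1.09 against 0.198, 0.0940 and 0.270 in the young, control and combination groups. With the clock score as a covariate only 18 and 19 mirrored genes stayed called, and since groups account for 66.9% of that score's variance, an unrecorded difference between the groups may still contribute beside an effect of the antibodies.

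Platelet genes higher in aged than in young lungs were weighed against blood content and scaling. More blood as the whole cause is argued against by the erythroid genes, whose mean log2 fold change was -0.12 where the platelet median was 1.82. Scaling moves the fold changes of all genes alike, so it cannot set platelet genes (median 1.82) apart from the median of all genes (-0.00693). TMM itself holds that median of all genes near 0, so whether all genes shifted together is not decided. The platelet median was at least 1.83 under 3 other scalings. Those moved the median of all genes only to between -0.00409 and 0.0293, so that outcome was fixed in advance. Age itself stays open and was not tested apart from the group, since each age under anti-PD-1 is 1 group of 3 libraries.

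Ribosomal protein genes lower with anti-PD-1 and higher in the combination were weighed against a length and GC content trend and scaling. The median in the combination was 0.41 with the trend removed, where it was 0.55 as reported, which argues against that trend as the whole cause. It was at least 0.35 under 3 other scalings. Scaling moves all genes alike: the median of all genes was -0.00863 as reported and -0.21 with library totals alone. That outcome was therefore fixed in advance. It shows only that scaling cannot set ribosomal protein genes apart from the median of all genes. RNA composition stays open: mitochondrial and non-polyadenylated transcripts also rose in the combination group, and no label records RNA quality. The anti-PD-1 comparison goes against it. With anti-PD-1, where ribosomal protein genes fell, the mitochondrially encoded list had a median of 0.00484 (camera adjusted p 0.984; -0.22 to 0.19 when 1 library was left out). Control and combination libraries gave 5.84 ± 0.260% and 5.89 ± 0.595% of their counts to ribosomal protein genes. Mitochondrial shares were 8.56 ± 1.62% and 13.4 ± 1.72% (SD, n = 3). These are shares of all counts, so a higher mitochondrial share itself lowers the ribosomal one. The TMM factors of the 2 groups also differed, at 0.986 ± 0.0274 and 0.925 ± 0.0516. The near-equal ribosomal shares therefore do not decide the question.

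Other splits of the same libraries were run for each count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many called genes as the real 2830, 2025 and 1674 were found in 1, 1 and 1 of the splits, the real one included, and the highest of the others was 0 in each; in the last comparison the real count was 0, reached by all 10, with a highest other of 1. As many lists as the real 30, 25, 11 and 26 were called in 2, 4, 9 and 1 of 10 splits, with a highest other of 30, 28, 26 and 25. For the overlaps 100 splits of 9 libraries were drawn, and 1 of 100, the real one, gave as many genes in each case. Splits that mix the aged anti-PD-1 libraries with others shared at most 1 gene, so this shows mainly that these 3 libraries stand apart. It does not exclude chance for the mirrored overlaps. Nor does it for those of age and anti-PD-1, where no other drawn split kept these 3 libraries as the shared group. The real overlaps were 513, 551, 437 and 345 and the highest others 452, 483, 1 and 0. The high values among the others came from the 2 splits that kept the 3 aged anti-PD-1 libraries as the shared group, which gave 452 and 483 or 443 and 439 mirrored genes.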
